A study of Mus musculus with 12 samples.

How the data were processed

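RNA was measured by stranded total RNA sequencing of 12 libraries from sorted mouse cells, in 6 groups of 2 biological replicates. The groups were 3 sorted populations, each with and without doxycycline. Per the labels, the libraries were sequenced paired-end in a single pool on a NextSeq 500. Per the labels, the authors used Trimmomatic 0.32, HISAT2 2.1.0 and StringTie 1.3.3 with the mouse genome build mm10. The annotation, the strand setting and the sort gates are not given in the sources used here.

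The deposited files held 1 value per gene name and no header. The values were read as FPKM (fragments scaled by transcript length and by mapped fragments) made by the authors with StringTie, an inference from the tool named and from the sums. The sums ran from 468326 to 579055 per library, where TPM would give every library the same sum, and the values were not whole numbers as read counts would be. Each file held 35976 gene names, and values of the 2 to 4 repeated names per file were added. The files gave no read counts, so the absolute depth is unknown. The smallest nonzero steps of low FPKM values gave a depth relative to the median library of 0.581 to 1.595, and 55 of 66 pairs of libraries gave the same ratio as this scale within 0.1 on the log2 scale.

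Genes with an FPKM of at least 1 in at least 2 of the 12 libraries were tested, which left 13316 genes. The values were log2-transformed after adding 1, so that the folds of genes near 0 FPKM depend on this pseudocount. limma 3.58.1 in R 4.3.3 was fitted to all 12 libraries with 6 group means and an intensity trend in the empirical Bayes step, with 6 residual degrees of freedom and a prior of 5.83. The comparisons were PlusDox against NoDox in each population, the 3 differences between those effects, and the steps HE2 against HE1 and HP against HE2 with and without doxycycline. P-values were two-sided and adjusted by the Benjamini-Hochberg method in each comparison, and a gene was called at an adjusted p below 0.05. The p-values rest on the spread between the 2 biological replicates, pooled over all 6 groups and moderated over genes. They do not rest on the groups compared alone. The labels describe the replicates no further. Differences between replicates correlated by number between groups (−0.1 to 0.526), so the residual degrees of freedom may not be independent. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 read the files and drew the plots.

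The test, the filter, the comparisons, 21 gene lists and the rule for named genes were fixed before the data were examined. The lists covered endothelial genes, Notch and arterial genes, haematopoietic transcription factors, pan-haematopoietic, erythroid, megakaryocyte, myeloid and stem-cell-associated genes, and genes linked to EVI1. They also covered DNA replication, mitosis, inhibitors of cyclin-dependent kinases with D cyclins, p53 targets, the TGF-beta and BMP response and immediate early genes. The others were the integrated stress response, interferon and inflammation, mesenchymal and smooth muscle genes, cardiac mesoderm, pluripotency and 3 surface genes often used in such sorts. Lists with at least 5 tested members, 19 in all, were tested against all other genes with camera of limma at a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data. Camera p-values were adjusted over the lists of a comparison. With the estimated correlation no fixed list passed in any comparison. This includes the HE2 to HP steps, where most endothelial genes were called lower on their own. A list call lost in that check is therefore not shown to be without change.

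Named genes with doxycycline were Runx1, Mecom, the 10 largest rises and 10 largest falls, and up to 4 called members of each list. The largest changes were taken among called genes with a mean FPKM of at least 5 in one group and both libraries of one group above both of the other. The steps and the differences between effects used 5 in each direction, and the separation of libraries was not asked of the differences. Predicted genes and small non-coding fragments were counted and not named. Hprt in HE2, Lars2, Mir6236, LOC101056014, Ctsj, Gm34865 and the genes called in all 3 populations were named after their values were seen. Coordinates came from a RefSeq table for mm10, in which 32501 of the 35976 names were found.

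The fit was tested on simulated data with 13316 genes of which 200 were changed in each of 3 runs. It recovered 44%, 55% and 49% of 2-fold changes and 89%, 91% and 92% of 4-fold changes in HE1, HE2 and HP. There were 0 calls of the wrong sign and 8, 8 and 15 false calls. The changed genes had a mean FPKM of at least 5, all groups started from the same mean, and the noise was independent between libraries. The real libraries also differed by class and replicate number, so these rates need not hold for them.

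Alternatives were a pseudocount of 0.1, no filter on low values, quantile normalization, scaling to a common median ratio, no intensity trend, a fold threshold, a fit to only the groups compared, and leaving out each library in turn. A lone library left in a group was assumed to vary like the other groups. A term for a class of libraries high in Lars2, and leaving these libraries out, were added after seeing the data. Scaling the FPKM of each library to a common sum, as TPM does, was not run. No cells without the construct were treated with doxycycline in the samples used here, so effects of the drug and of the induced construct were not separated.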

Results

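The data were gene expression values from mouse A2lox.cre embryonic stem cells, a line built to take up a doxycycline-inducible gene at a fixed site, here RUNX1-EVI1. This leukaemia-associated fusion joins RUNX1, a transcription factor needed to form blood cells, to EVI1, a zinc finger protein encoded by the Mecom gene. FLK1-positive cells were cultured towards blood, received 0 or 0.5 µg/ml doxycycline for 18 hours and were sorted into hemogenic endothelium 1 (HE1), hemogenic endothelium 2 (HE2) and hematopoietic progenitors (HP). Hemogenic endothelium is the vascular tissue from which the first blood cells arise. Each of the 6 groups had 2 libraries, and PlusDox and NoDox name cells with and without doxycycline. The series title asks how the fusion affects lineage choice and the cell cycle. Between 11461 and 12174 genes reached 1 FPKM per library, and 14295 to 18837 names were listed at 0. The depth relative to the median library was lowest in PlusDox HE1 replicate 2 (0.581), PlusDox HP replicate 2 (0.642) and NoDox HP replicate 2 (0.708) and highest in PlusDox HE1 replicate 1 (1.595). Of 3781 genes with a median of at least 20 FPKM, 4 were listed at 0 in at least 1 library.

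The sorted population set most of the variation between libraries. The first principal component held 64.6% of the variance and ran from HE1 (−61.9 to −46.8) through HE2 (−20.6 to 11.2) to HP (55.1 to 71.3). Across genes, the replicates of a group had a Pearson r of 0.973 to 0.983, and genes are not independent replicates. In 5 libraries, Lars2 (mm10 chromosome 9, 123366927 to 123462675, protein coding), Mir6236 and LOC101056014 were far higher than in the other 7. Lars2 stood at 10224 to 19970 FPKM against 24.0 to 224 FPKM, and the 3 features took 8.81% to 16.9% of the summed FPKM against 0.35% to 0.59%. The 5 libraries were NoDox HE1 replicate 1, NoDox HP replicate 2 and replicate 2 of each PlusDox group, so that both doxycycline groups of HE1 and of HP held 1 each, while in HE2 only PlusDox held one.

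**Figure D1:**
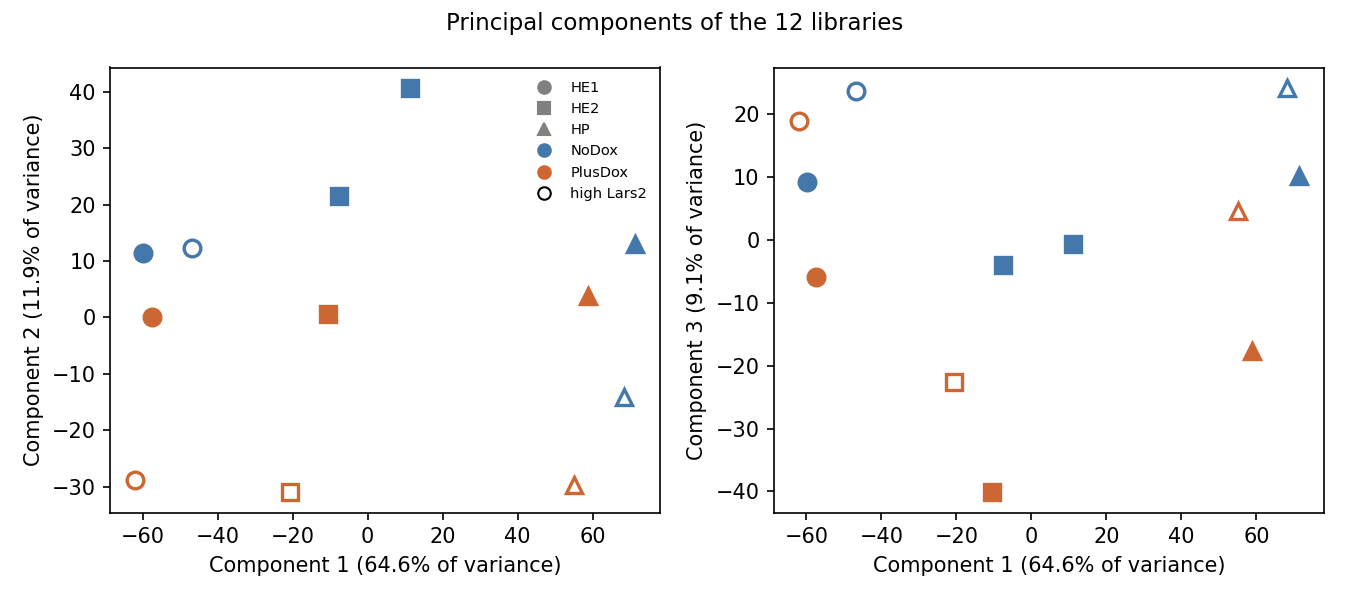
Principal components of the log2 values of 13316 genes, with component 1 on the x axis and components 2 and 3 on the y axes (percent of variance in the labels), one point per library. Shapes mark the sorted population, colours mark doxycycline, and open points are the 5 libraries high in Lars2. Component 1 (64.6%) orders HE1, HE2 and HP.

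The first question was how the genes that give the fusion its parts read out with doxycycline. The construct was taken to be a human cDNA, whose reads may map only in part to mouse Runx1 and Mecom. A flat value of either gene therefore does not show a lack of induction. Mecom (mm10 chromosome 3, 29951296 to 30509759, protein coding) rose in HP from 0.1996 ± 0.00811 to 5.34 ± 0.238 FPKM (mean ± SD, n = 2 here and for all FPKM values). Its log2 fold change was 2.40 ± 0.32 (SE, as for all folds; adjusted p = 0.0058, limma), or 4.18 with a pseudocount of 0.1. In HE2, Mecom read 10.0 ± 5.56 and 19.3 ± 1.25 FPKM (log2 0.98 ± 0.32, limma adjusted p = 0.0923), and in HE1 22.6 ± 8.01 and 20.5 ± 3.44 FPKM (log2 −0.10 ± 0.32, adjusted p = 0.986). Runx1 (mm10 chromosome 16, 92601466 to 92826074, protein coding) passed the limma test in no population. It read 2.49 ± 1.53 and 2.49 ± 2.12 FPKM in HE1 (log2 −0.07 ± 0.57, adjusted p = 0.995, limma). Runx1 read 33.1 ± 5.23 and 28.6 ± 10.2 in HE2 (−0.24 ± 0.57, 0.847), and 61.7 ± 8.05 and 38.6 ± 33.1 in HP (−0.97 ± 0.57, 0.72). Hprt, a purine salvage enzyme gene on chromosome X (52988078 to 53021660, protein coding), rose in all 3 populations by limma. It went from 1.78 ± 0.469 to 32.2 ± 18.2 in HE1, from 4.40 ± 1.10 to 37.4 ± 1.49 in HE2 and from 5.88 ± 1.64 to 65.9 ± 23.3 FPKM in HP. The Mecom call in HP was lost without NoDox HP replicate 1 (log2 2.40, limma adjusted p = 0.0614), NoDox HP replicate 2 (2.41, 0.0576) or PlusDox HP replicate 2 (2.36, 0.0561). In HE2 Mecom passed limma without NoDox HE2 replicate 2 (1.52, 0.0136) and stood at 0.44 (0.607) without NoDox HE2 replicate 1. The Runx1 fold turned positive without PlusDox HP replicate 2 (0.01), PlusDox HE2 replicate 2 (0.12), NoDox HE1 replicate 1 (0.39) or PlusDox HE1 replicate 2 (0.59), and that of Mecom in HE1 without NoDox HE1 replicate 2 (0.25) or PlusDox HE1 replicate 2 (0.07).

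**Figure D2:**
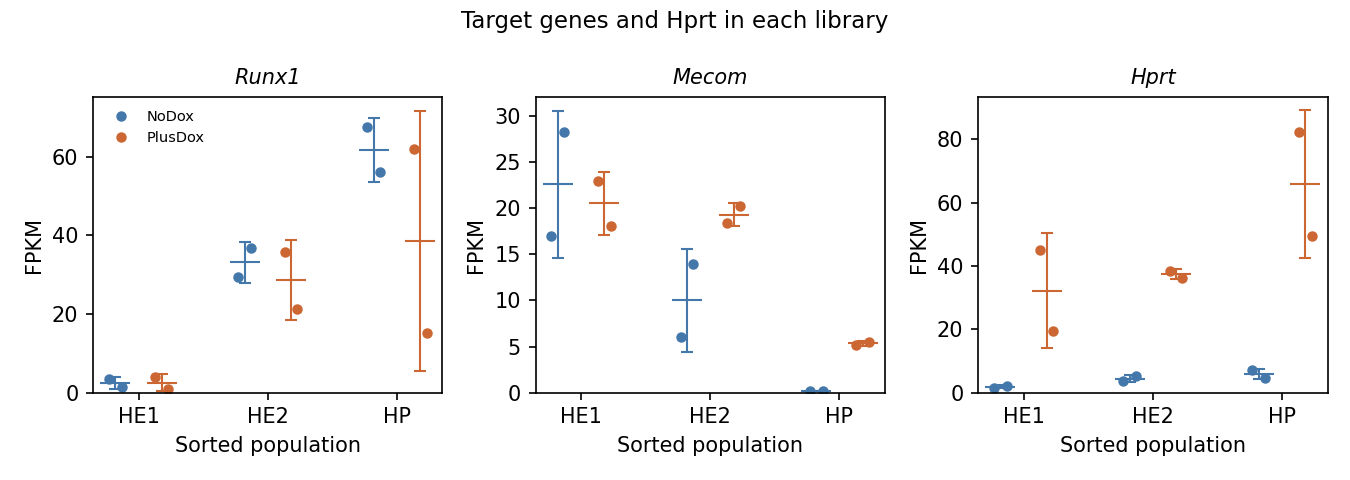
FPKM (y axis) of Runx1, Mecom and Hprt by sorted population (x axis) and doxycycline (colour); points are the 2 libraries, the dash their mean and the bar ± SD. Mecom in HP went from 0.1996 to 5.34 FPKM, while the 2 PlusDox HP libraries gave 62.0 and 15.2 FPKM of Runx1.

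In HE1, doxycycline raised Cxcr4 and Dll4 and lowered Bmp2, Aplnr and Has2. Cxcr4, a chemokine receptor, rose from 1.31 ± 1.19 to 6.77 ± 0.440 FPKM (log2 1.85 ± 0.38), and Dll4, a Notch ligand of arterial endothelium, from 4.46 ± 2.15 to 18.4 ± 6.97 FPKM (1.84 ± 0.40). Bmp2, a bone morphogenetic protein, fell from 32.4 ± 11.4 to 5.62 ± 2.40 FPKM (−2.34 ± 0.32). Aplnr, the apelin receptor, fell from 111 ± 10.1 to 24.6 ± 1.51 (−2.13 ± 0.31), and Has2, a hyaluronan synthase, from 26.6 ± 14.7 to 5.04 ± 3.56 (−2.22 ± 0.43). Cdkn1c and Cdkn2b, inhibitors of cyclin-dependent kinases, rose by 1.58 ± 0.28 and 1.48 ± 0.23. The largest rises after Hprt (3.47 ± 0.36) were Nts, which encodes neurotensin (3.07 ± 0.62), St6galnac2, Ctsh, Ltb, Mall, Prom1, Lgr6, Spint2 and Mogat2 (2.65 down to 2.32). The other large falls were Oit3, Samsn1, Ptgs1, Gas7, Syt13, Slc1a2 and F2rl3 (−2.01 to −1.57). Single members of other lists rose as well, with Vwf, von Willebrand factor, at 1.40 ± 0.23, Cd68 at 1.21 ± 0.21, Myl9 at 1.22 ± 0.20 and Laptm5 at 1.17 ± 0.25. With limma, 182 of 13316 genes passed the adjusted threshold, 128 higher and 54 lower, and 1277 had an unadjusted p below 0.05. Without NoDox HE1 replicate 1, NoDox HE1 replicate 2, PlusDox HE1 replicate 1 or PlusDox HE1 replicate 2 the count was 2, 94, 61 or 116, of which 2, 76, 28 or 103 were higher, and 2, 24, 15 or 19 of the 31 called named genes remained called. The 7 libraries low in Lars2 alone, with 1 residual degree of freedom, gave 0 calls in limma and 573 genes at an unadjusted p below 0.05.

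Among the fixed lists in HE1, the Notch and arterial list had the smallest camera p. Cxcr4, Dll4, Jag1 (1.18 ± 0.23) and Bmx (1.14 ± 0.24) rose, 4 of 19 tested members, or 8 adjusted over the list alone, and 15 did not pass over all genes. The median of this list was 0.33 (camera adjusted p = 3.31e-07; adjusted p = 0.792 with an estimated correlation). Ier3 (0.91 ± 0.20) was the 1 of 19 immediate early genes that rose, with 5 adjusted over the list alone (median 0.45, camera adjusted p = 1e-05; adjusted p = 0.792 with an estimated correlation). No gene of the mitosis list (0 of 30, and 0 adjusted over the list alone; median −0.36, camera adjusted p = 4.49e-07) or of the DNA replication list (0 of 36, and 0 adjusted over the list alone; −0.30, 2.63e-06) passed on its own. On average both lists lay lower than the other genes by camera, at the preset correlation only (adjusted p = 0.805 with an estimated correlation for both). The EVI1-linked list also passed at the preset correlation (0 of 15 members, 1 adjusted over the list alone; median 0.13, camera adjusted p = 0.0127; adjusted p = 0.792 with an estimated correlation). So did the interferon list (0 of 22, 0 adjusted over the list alone; median 0.18, camera adjusted p = 0.0127; adjusted p = 0.806 with an estimated correlation). The surface genes Kit, Tek and Itga2b read 42.0 ± 2.19, 153 ± 14.9 and 40.1 ± 15.5 FPKM without and 26.7 ± 7.68, 94.9 ± 17.3 and 17.3 ± 9.69 FPKM with doxycycline. None of the 3 passed over all genes, and 3 were lower adjusted over the list alone. The other 13 lists had camera adjusted p from 0.188 to 0.936 and the 4 tested pluripotency genes did not pass. Medians of the endothelial, pan-haematopoietic, erythroid, megakaryocyte and myeloid lists were 0.10, 0, −0.03, −0.14 and −0.02, and those of the cell cycle inhibitor and p53 target lists −0.03 and 0.05. The interferon call was lost without NoDox HE1 replicate 1 (camera adjusted p = 0.781) or PlusDox HE1 replicate 2 (0.884) and with median scaling (0.0567), and the EVI1-linked call without NoDox HE1 replicate 2 (0.0783) or PlusDox HE1 replicate 1 (0.0561). In the low and high Lars2 classes the Notch medians were 0.43 and 0.64, the mitosis medians −0.16 and −0.62 and the interferon medians −0.15 and 0.74.

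**Figure D3:**
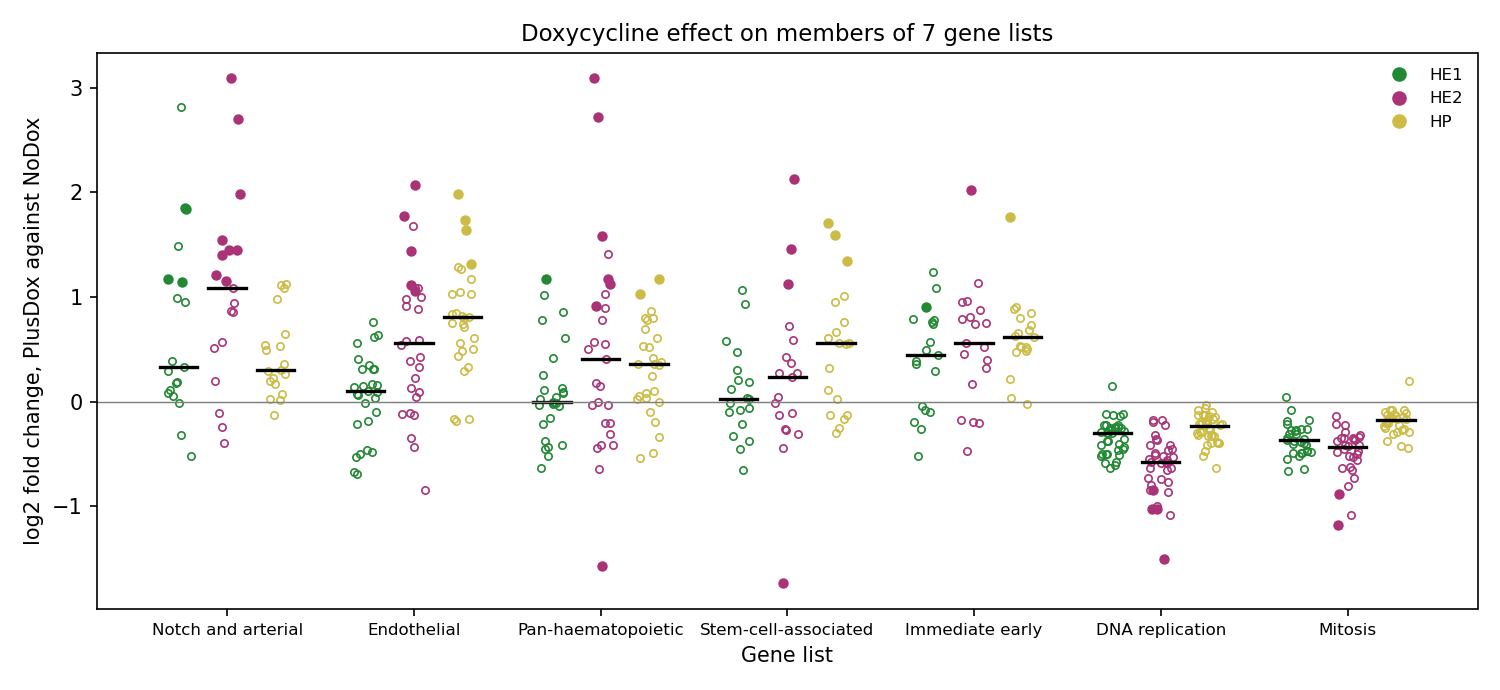
Log2 fold change with doxycycline (y axis) of each tested member of 7 gene lists (x axis) in HE1, HE2 and HP (colours); filled points passed the limma test, open points did not, and black bars are medians. The endothelial medians were 0.10, 0.56 and 0.81 in HE1, HE2 and HP, and the DNA replication medians −0.30, −0.57 and −0.23.

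In HE2, doxycycline raised Ctsh, Il1b, Coro1a, Ptprc and Procr and lowered Mpo. Ctsh, a lysosomal protease, rose from 0.751 ± 0.706 to 34.2 ± 2.90 FPKM (log2 4.39 ± 0.31). Il1b, an inflammatory cytokine, rose from 0.0611 ± 0.0377 to 18.3 ± 3.79 (4.17 ± 0.39), and Coro1a, a leukocyte actin regulator, from 5.21 ± 2.14 to 50.4 ± 6.63 (3.09 ± 0.32). Ptprc, the pan-leukocyte antigen, rose from 0.879 ± 0.409 to 11.6 ± 4.51 FPKM (2.72 ± 0.27), and Procr, a surface protein of blood stem cells and arterial endothelium, from 30.8 ± 9.71 to 135 ± 10.7 (2.13 ± 0.24). Mpo, the granule enzyme of neutrophil precursors, fell from 15.5 ± 1.99 to 2.34 ± 0.984 FPKM (−2.33 ± 0.27). Mogat2, Smtnl1, Pdzk1ip1, Tspan8, Nts, Gja5 and Ltb were the other large rises (3.96 down to 3.07), and Hprt rose by 2.84. Kctd12, Mrpl12, Igfbp5, Rnd2, Anp32b, Fzd10, Txn2 and Syt13 were among the large falls (−3.67 to −1.97). Rps16 had the lowest fold (−3.995 ± 0.78). This ribosomal protein gene has many processed copies, and its NoDox HE1 libraries gave 328 ± 329 FPKM. With limma, 807 genes passed, 509 higher and 298 lower, and 2973 had an unadjusted p below 0.05. Without NoDox HE2 replicate 1 the count was 172 and without PlusDox HE2 replicate 2 it was 238, with 30 and 36 of the 62 called named genes still called. The HE2 count was 1254 with a term for library class and 7 in the 7 libraries low in Lars2. The share of called genes that were higher was 63.1%, but 51.6% with quantile normalization, 53.5% with median scaling and 48.5% without PlusDox HE2 replicate 1.

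By list in HE2, the Notch and arterial genes had the largest median. Of 19 Notch and arterial genes 9 rose, or 12 adjusted over the list alone, led by Gja5 (3.09 ± 0.69), a gap junction gene of arteries, Cxcr4 (2.70 ± 0.38), Dll4 (1.99 ± 0.40) and Jag1 (1.55 ± 0.23). The median was 1.09 (camera adjusted p = 6.3e-09). Of 28 endothelial genes 5 rose, or 11 adjusted over the list alone, among them Nos3, endothelial nitric oxide synthase (2.07 ± 0.27), Cldn5 (1.78 ± 0.44) and Stab1 (1.44 ± 0.31; median 0.56, camera adjusted p = 1.53e-05). The pan-haematopoietic list had 6 of 27 genes higher and 1 lower (10 and 2 adjusted over the list alone; median 0.41, camera adjusted p = 0.00255), with Spn up (1.58 ± 0.21) and Ptpn7 down (−1.57 ± 0.29). Il1b and Ifitm1 (2.58 ± 0.45) were the 2 of 22 interferon and inflammation genes that rose (2 adjusted over the list alone; median 0.36, camera adjusted p = 0.0047). Nr4a1 (2.02 ± 0.31) was the 1 of 19 immediate early genes that did (10 adjusted over the list alone; 0.56, 4.86e-05). Of 36 DNA replication genes 4 fell, or 18 adjusted over the list alone (median −0.57, camera adjusted p = 1.87e-10). They were Rrm2, a ribonucleotide reductase subunit, which fell from 80.9 ± 8.83 to 28.4 ± 7.46 FPKM (−1.50 ± 0.23), Ccne1, cyclin E1 (−1.02 ± 0.24), Uhrf1 and Mcm4. Aurka, a mitotic kinase (−1.18 ± 0.22), and Birc5 (−0.88 ± 0.17) were the 2 of 30 mitosis genes that fell, with 5 adjusted over the list alone (median −0.43, camera adjusted p = 7.79e-08). None of these 7 calls held with an estimated correlation (adjusted p = 0.817 with an estimated correlation for each).

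In the other 12 tested lists of HE2 (camera adjusted p from 0.0527 to 0.972), single genes moved in both directions. The myeloid list had 6 of 22 genes higher and 3 lower (7 and 3 adjusted over the list alone), with Clec7a (1.98 ± 0.43) and Tyrobp (1.95 ± 0.28) up and Mpo down. The megakaryocyte list had 2 of 24 higher (Vwf, 1.58 ± 0.23, and Selp, 1.16 ± 0.24) and 3 lower, among them F2rl2 (−1.74 ± 0.25), with 3 and 4 adjusted over the list alone. The blood transcription factors Spi1, a driver of myeloid fate (1.34 ± 0.27), Bcl11a (1.26 ± 0.26) and Cebpa (0.78 ± 0.20) were the 3 of 23 that rose, with 3 adjusted over the list alone. Of the stem-cell-associated list Procr, Ly6a (1.46 ± 0.27) and Angpt1 (1.13 ± 0.21) rose, the 3 of 19 genes that did (3 adjusted over the list alone). Alas2, the first enzyme of erythroid haem synthesis, fell (−1.43 ± 0.22) and Rhag rose (1.83 ± 0.18) among 24 erythroid genes (1 and 1 adjusted over the list alone). Cdkn1c (1.95 ± 0.28), Trib3 (1.22 ± 0.30) and Sesn1 (0.83 ± 0.22) rose, and Tgfb1 (−1.25 ± 0.31), Perp (−0.96 ± 0.19), Pdgfrb (−1.25 ± 0.27) and Tnnt2 (−1.64 ± 0.26) fell in lists that did not pass. The interferon call in HE2 was lost without NoDox HE2 replicate 1 (camera adjusted p = 0.536), without PlusDox HE2 replicate 2 (0.279) and with the library class term (0.177), and the pan-haematopoietic call with that term (0.0506).

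**Figure D4:**
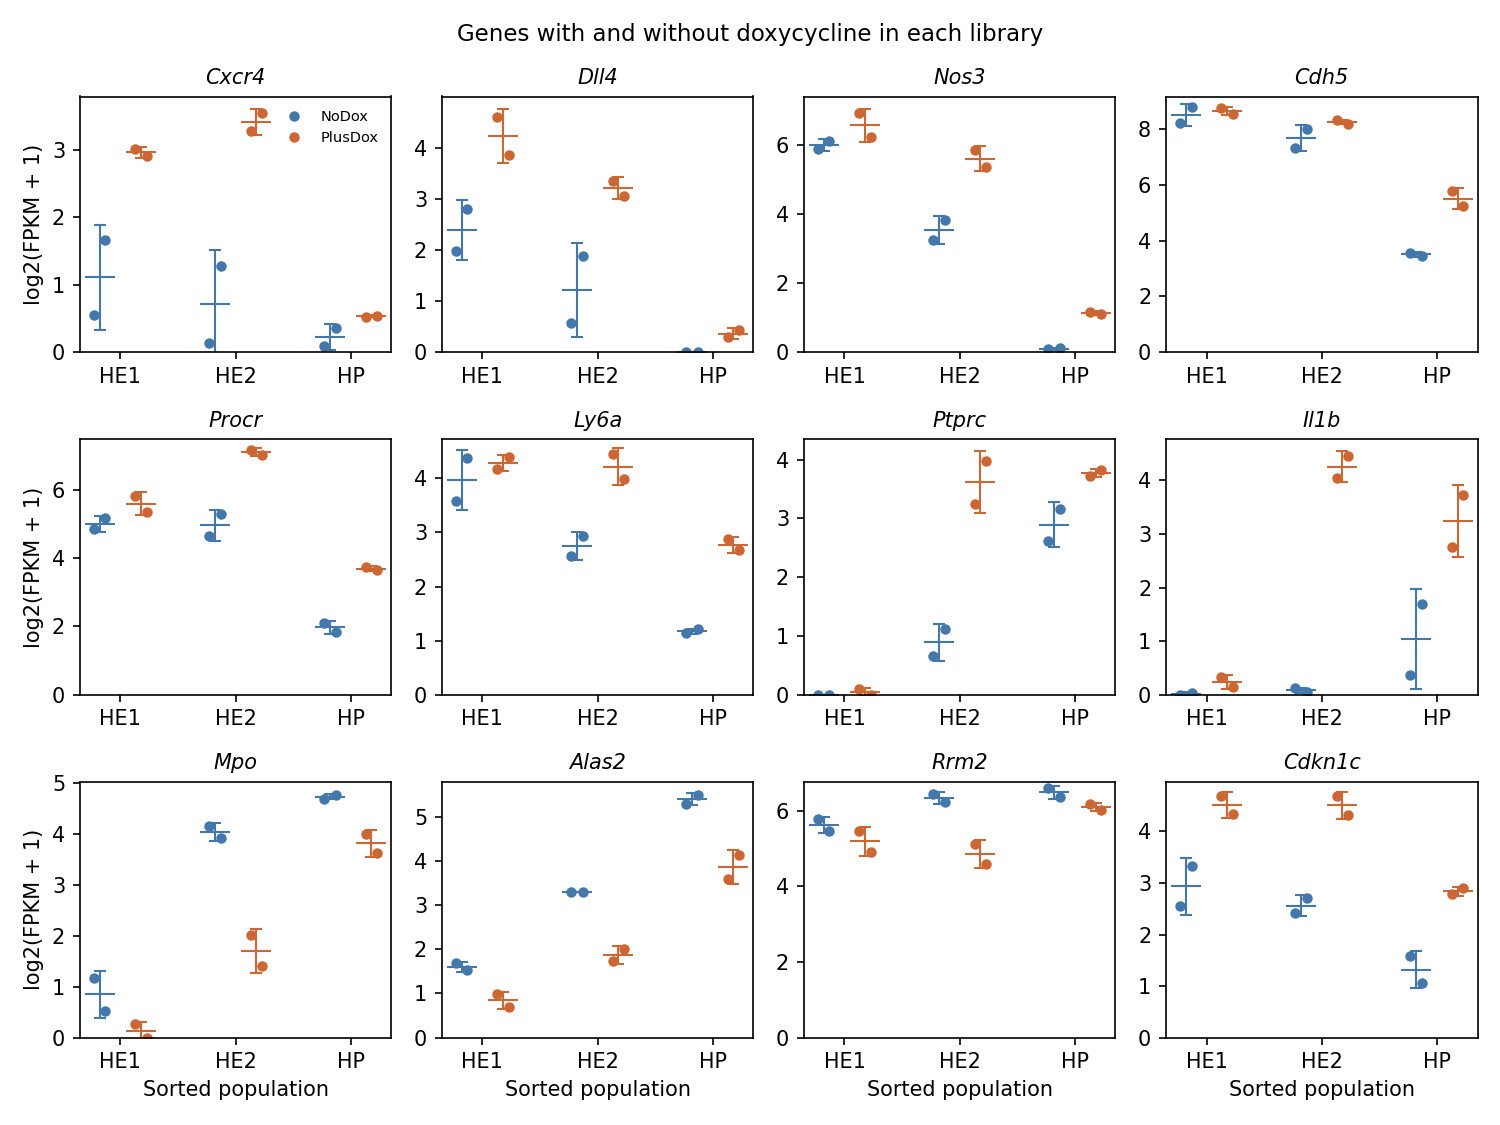
Log2(FPKM + 1) (y axes) of 12 named genes by sorted population (x axes) and doxycycline (colour); points are the 2 libraries, the dash their mean and the bar ± SD. Cxcr4 rose in HE1 and HE2, Cdh5 rose in HP from 10.4 to 44.8 FPKM, and Mpo fell in HE2 from 15.5 to 2.34 FPKM.

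In HP, doxycycline raised Cdh5 and Procr and lowered Alas2 and Aqp8. Cdh5, VE-cadherin, the adhesion protein of endothelial junctions, rose from 10.4 ± 0.677 to 44.8 ± 11.8 FPKM (log2 1.99 ± 0.26), and Procr from 2.96 ± 0.516 to 11.9 ± 0.681 (1.71 ± 0.24). Alas2 fell from 41.5 ± 4.22 to 13.9 ± 4.00 FPKM (−1.54 ± 0.22), and Aqp8, a water channel gene, from 13.2 ± 2.05 to 3.16 ± 0.988 (−1.79 ± 0.37). Ccnd1, cyclin D1, rose from 2.21 ± 0.379 to 9.83 ± 2.77 FPKM (1.73 ± 0.31), as did Cdkn1c (1.52 ± 0.28). The largest rises were Hprt (3.26 ± 0.36), the metallothionein Mt2 (3.21 ± 0.52), Pdzk1ip1, Mecom, Mogat2, Il1b, Trim47, Acer2, Thsd1 and Rhag (2.91 down to 1.99), and the other large falls Hsd3b1, Slc38a5, BC021767, Samd14, Mylk3, Efnb1, Tmcc2 and Bag5 (−1.50 to −1.22). With limma, 111 genes passed, 80 higher and 31 lower, and 1250 had an unadjusted p below 0.05. The count was 10 without NoDox HP replicate 1, 25 without NoDox HP replicate 2, 49 without PlusDox HP replicate 1, 18 without PlusDox HP replicate 2 and 64 without either NoDox HE1 library. Of the 34 called named genes 3, 7, 15, 8 and 29 were still called in these fits. The count was 175 with the library class term and 3 in the 7 libraries low in Lars2. With a pseudocount of 0.1 it was 92, of which 84 were higher, 8 were lower and 60 were among the 111.

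Among the fixed lists in HP, the endothelial list had the smallest camera p. Cdh5, Ramp2 (1.74 ± 0.22), Egfl7 (1.64 ± 0.22) and Sox18 (1.32 ± 0.21) rose, 4 of 28 genes, or 16 adjusted over the list alone, with a median of 0.81 (camera adjusted p = 3.12e-17). Nr4a1 (1.76 ± 0.31) was the 1 of 19 immediate early genes that rose (4 adjusted over the list alone; median 0.62, camera adjusted p = 1.19e-08). Procr, Ly6a (1.598 ± 0.27) and Fgd5 (1.35 ± 0.25) were the 3 of 19 stem-cell-associated genes that rose (8 adjusted over the list alone; 0.56, camera adjusted p = 4.2e-06). These 3 calls had adjusted p = 0.366 with an estimated correlation. Of the DNA replication list (median −0.23, camera adjusted p = 2.74e-06), the mitosis list (−0.17, 0.000488), the Notch and arterial list (0.30, 0.000239), the myeloid list (0.29, 0.00653), the blood transcription factor list (0.16, 0.0196) and the EVI1-linked list (0.18, 0.0499) no member passed over all genes. In these 6 lists 0, 0, 4, 0, 1 and 1 passed adjusted over the list alone. Spn (1.17 ± 0.21) and Dock2 (1.03 ± 0.21) were the 2 of 27 pan-haematopoietic genes that rose (2 adjusted over the list alone; 0.36, camera adjusted p = 0.000388). Ccnd1 and Cdkn1c were the 2 of 15 that rose in the cell cycle inhibitor and D cyclin list (3 adjusted over the list alone; median 0.29, camera adjusted p = 0.0049), and Il1b the 1 of 22 in the interferon list (1 adjusted over the list alone; 0.23, 0.00687). These 9 calls had adjusted p = 0.536 to adjusted p = 0.609 with an estimated correlation. Selp (1.44 ± 0.24) and Id3 (1.26 ± 0.21) rose in lists that did not pass, and the other 7 tested lists had camera adjusted p from 0.1 to 0.645. Without NoDox HP replicate 1 the transcription factor, pan-haematopoietic, myeloid, EVI1-linked and interferon calls were lost (camera adjusted p = 0.246, 0.301, 0.805, 0.329 and 0.817). Without PlusDox HP replicate 2 the transcription factor, myeloid, EVI1-linked, kinase inhibitor and interferon calls were lost (0.146, 0.507, 0.185, 0.122 and 0.78). The EVI1-linked call was also lost without either NoDox HE1 library (0.0534) or either NoDox HE2 library (0.0619), with median scaling (0.0719), with the class term (0.0645) and with a pseudocount of 0.1 (0.104). That pseudocount also ended the myeloid (camera adjusted p = 0.0611) and transcription factor (0.0526) calls. The endothelial medians were 0.88 and 0.72 in the low and high Lars2 classes.

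Whether doxycycline acted differently between populations was tested on the differences between effects. Il1b gained more in HE2 than in HE1 (difference of log2 folds 3.96 ± 0.55), as did Naaa, a lysosomal amidase gene (2.16 ± 0.28). Tirap, an adaptor of Toll-like receptors, went from 4.13 ± 0.767 to 13.8 ± 1.75 FPKM in HE1 and from 7.48 ± 0.666 to 4.87 ± 0.139 in HE2 (−2.06 ± 0.27). Ptprc, listed at 0 in both NoDox HE1 libraries, also passed. Ctsh gained less in HP than in HE2 (−3.60 ± 0.44), and Ramp2, a receptor-modifying protein of endothelium, went from 568 ± 70.3 to 359 ± 65.7 FPKM in HE1 and from 4.64 ± 0.509 to 17.8 ± 0.0745 in HP (2.40 ± 0.31). Rhag gained more in HE2 (1.80 ± 0.26) and in HP (1.96 ± 0.26) than in HE1, and Zfp185 (−2.73 ± 0.38) less in HP than in HE1; Mall, listed at 0 in both NoDox HP libraries, passed there too. limma called 6 genes for HE2 against HE1 (5 higher and 1 lower; adjusted p = 0.0397 for each), 2 for HP against HE2 (1 and 1; 0.0231) and 5 for HP against HE1 (3 and 2; 0.048). There were 892, 875 and 869 genes at an unadjusted p below 0.05. These 3 comparisons share effects and are not independent. With quantile normalization 70.0% of the HE2 against HE1 calls and 35.7% of the HP against HE1 calls were higher (83.3% and 60.0% without it), and with median scaling the 1 gene called for HE2 against HE1 was lower. For HE2 against HE1 the count was 0 without either NoDox HE1 library, either NoDox HE2 library, PlusDox HE1 replicate 2 or either PlusDox HP library, 1 without either NoDox HP library or PlusDox HE1 replicate 1 and 2 without PlusDox HE2 replicate 2. For HP against HE2 it was 0 without either NoDox HE1 library, either NoDox HP library or PlusDox HP replicate 1, 1 without either NoDox HE2 library, PlusDox HE2 replicate 2 or PlusDox HP replicate 2, and 5 without PlusDox HE2 replicate 1. For HP against HE1 it was 0 without any NoDox HE1, NoDox HP or PlusDox HP library or PlusDox HE1 replicate 1, and 3 without PlusDox HE1 replicate 2.

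By list, and at the preset correlation only, effects of doxycycline on endothelial genes averaged higher in HE2 (median difference 0.52, camera adjusted p = 2.49e-05) and in HP (0.78, 8.2e-11) than in HE1. Those on Notch and arterial genes averaged higher in HE2 than in HE1 (0.37, camera adjusted p = 0.0155) and lower in HP than in HE2 (−0.37, 0.000312). Effects on the DNA replication list averaged lower in HE2 than in HE1 (−0.24, camera adjusted p = 0.000836) and higher in HP than in HE2 (0.34, 0.000363). Those on the mitosis list also averaged higher in HP than in HE2 (0.28, camera adjusted p = 0.00117). No member of these 2 lists passed alone. The pan-haematopoietic list differed between HE2 and HE1 (0.37, camera adjusted p = 0.0154), the erythroid (−0.27, 0.00631) and megakaryocyte (0.36, 0.0325) lists between HP and HE2, and the stem-cell-associated list between HP and HE1 (0.52, 0.0104). Of their members only Ptprc of the pan-haematopoietic list and Ramp2 of the endothelial list in HP against HE1 passed over all genes. Adjusted over the list alone, the members passing in the direction of the list were 2, 0, 3 and 0 for the endothelial, Notch, pan-haematopoietic and DNA replication lists in HE2 against HE1. They were 8, 0, 1, 0 and 0 for the Notch, erythroid, megakaryocyte, DNA replication and mitosis lists in HP against HE2, and 8 and 5 for the endothelial and stem-cell-associated lists in HP against HE1. The list calls had adjusted p = 0.861, adjusted p = 0.922 and adjusted p = 0.97 with an estimated correlation in the 3 comparisons. In HE2 against HE1, all 4 calls were lost without NoDox HE2 replicate 1 (camera adjusted p = 0.18 to 0.697). The Notch and DNA replication calls were also lost without NoDox HE1 replicate 2 (0.342 and 0.0762) or PlusDox HE2 replicate 2 (0.0994 and 0.0724). The pan-haematopoietic call was lost without NoDox HE1 replicate 1 (0.126), with quantile normalization (0.0511), median scaling (0.0597) or the class term (0.185, with 0.0773 for Notch). In the other 2 comparisons, the Notch and DNA replication calls were lost without NoDox HE2 replicate 1 (0.0746 and 0.0684), and the Notch call with a pseudocount of 0.1 (0.0527). The megakaryocyte call was lost without NoDox HE2 replicate 2 (0.0919), NoDox HP replicate 1 (0.853), PlusDox HE2 replicate 1 (0.0803) or PlusDox HP replicate 2 (0.789), and with that pseudocount (0.119) or median scaling (0.0515). The erythroid call was lost without NoDox HP replicate 2 (0.135), PlusDox HE2 replicate 2 (0.379) or PlusDox HP replicate 1 (0.559), and with quantile normalization (0.118) or the class term (0.241). The stem-cell-associated call was lost without NoDox HP replicate 1 (0.0521) or PlusDox HE1 replicate 1 (0.0555) and with no filter (0.127).

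Doxycycline effects were compared between populations across genes. Cdkn1c, Hprt, Ltb, Mogat2, Nqo1, Pak1, Sh3bgrl2, Slc16a9 and Stk26 were the 9 genes called higher in all 3 populations. Nqo1, a quinone reductase, had folds of 1.29, 1.87 and 1.85 and Slc16a9, a carrier gene, of 1.47, 2.53 and 1.46 in HE1, HE2 and HP. HE1 and HE2 shared 94 genes called higher and 21 called lower, where independent lists would share 4.89 and 1.21. HE2 and HP shared 58 and 7 (3.06 and 0.694), with 1 gene called in opposite directions, and HE1 and HP shared 9 and 0 (0.769 and 0.126). Across the 13316 genes, which are not independent replicates, the Pearson r of the folds was 0.548 for HE1 and HE2, 0.499 for HE2 and HP and 0.32 for HE1 and HP (Spearman rho 0.462, 0.485 and 0.281). No library was shared within a pair of effects, but the effects may not be independent. Differences between replicates correlated by number at 0.415 to 0.526 between the PlusDox groups and −0.008 to 0.322 between the NoDox groups. Culture or batch effects common to the populations would raise the overlaps and r values too, and were not separated. Without PlusDox HP replicate 2 the r was 0.177 for HE1 and HP and 0.321 for HE2 and HP, and without NoDox HE1 replicate 1 it was 0.211 and without NoDox HP replicate 1 it was 0.324 for these pairs in turn. In the 7 libraries low in Lars2 it was 0.175 for HE1 and HP.

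Without doxycycline, HE2 differed from HE1 in gaining blood genes and losing endothelial and arterial ones. By median ratio the tested genes lay 0.18 higher in HE2 (log2, and 0.19 with doxycycline). The folds of the HE2 against HE1 steps are given relative to that shift, while the calls were made without taking it off. Itgb3, a platelet integrin, stood at 9.55 ± 0.439 FPKM in HE1 and 202 ± 0.582 in HE2 (log2 4.09 ± 0.20), and Plek at 1.15 ± 0.0999 and 50.6 ± 20.0 (4.35 ± 0.26). Adgrg1 stood at 3.19 ± 2.23 and 100 ± 34.9 (4.48 ± 0.52), and the blood transcription factor Myb at 2.27 ± 2.40 and 45.5 ± 15.6 (3.84 ± 0.51). Kctd12, listed at 0 in both NoDox HE1 libraries, was at 25.9 ± 5.09 FPKM. Cyp26a1, a retinoic acid hydroxylase (−2.83 ± 0.26), Ctsh (−2.82 ± 0.31), Nos3 (−2.65 ± 0.27) and Tnc, an extracellular matrix protein (−2.65 ± 0.34), were lower. Of the fixed lists, 20 of 24 erythroid genes were higher (23 adjusted over the list alone; relative median 1.45), 19 of 27 pan-haematopoietic (22; 1.25) and 15 of 23 transcription factor genes (16; 1.02). Higher as well were 14 of 24 megakaryocyte (16; 1.00), 9 of 22 myeloid (12; 0.53), 6 of 15 EVI1-linked (7; 0.28) and 6 of 36 DNA replication genes (19; 0.43). Lower were 13 of 28 endothelial (19 adjusted over the list alone; −1.15), 7 of 19 Notch and arterial (9; −0.98) and 4 of 12 cardiac mesoderm genes (6; −0.97). Camera adjusted p for these 10 lists ran from 2.65e-15 to 0.000264, and mitosis (0.00331), TGF-beta and BMP response (0.00659), integrated stress response (0.043) and mesenchymal genes (0.000135) passed too. No call held with an estimated correlation (adjusted p = 0.0768 to adjusted p = 0.653 with an estimated correlation). limma called 1348 genes, 755 higher and 593 lower, and the share higher was 56.0%, or 43.1% with quantile normalization, 36.3% with median scaling, 43.8% without NoDox HE1 replicate 1 and 46.5% without NoDox HE2 replicate 2. The count was 771 without NoDox HE1 replicate 1, 262 without NoDox HE1 replicate 2 (mitosis camera adjusted p = 0.0718, stress response 0.0816), 339 without NoDox HE2 replicate 1 (TGF-beta and BMP response 0.0562, stress response 0.323) and 53 in the 7 libraries low in Lars2. The stress response call was also lost with a pseudocount of 0.1 (camera adjusted p = 0.0675), no filter (0.0998) and the class term (0.103).

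From HE2 to HP without doxycycline, endothelial genes were lost and platelet and red cell genes gained. Ramp2 stood at 212 ± 52.7 FPKM in HE2 and 4.64 ± 0.509 in HP (log2 −5.22 ± 0.22), and the endothelial transcription factor Sox18 at 95.0 ± 15.6 and 2.87 ± 0.373 (−4.63 ± 0.21). Ptprb, Icam2 and Bcl6b were lower by similar folds (−4.59, −4.57 and −4.46). Pf4, platelet factor 4, stood at 0.660 ± 0.00491 and 27.5 ± 13.3 FPKM (4.02 ± 0.33), Tubb1, the platelet tubulin, at 4.67 ± 0.184 and 90.8 ± 21.1 (3.999 ± 0.22). Gp5 (3.2 ± 0.24), Tuba4a (3.18 ± 0.27) and the globin gene Hbb-bs (3.10 ± 0.42), whose reads can be shared with paralogs, were also higher. Lower were 26 of 28 endothelial genes (28 adjusted over the list alone; median −3.13) and 13 of 19 Notch and arterial genes (15; −1.68). Higher were 23 of 24 erythroid (23; 2.16), 15 of 24 megakaryocyte (20; 1.22), 16 of 22 myeloid (17; 1.18) and 14 of 27 pan-haematopoietic genes (18; 0.97), with camera adjusted p from 3.62e-30 to 1.15e-09. In all, 15 of 19 lists passed at the preset correlation and none with an estimated one (adjusted p = 0.074 to adjusted p = 0.471 with an estimated correlation). limma called 2125 genes, 707 higher and 1418 lower, and the share higher was 33.3%, or 47.9% with quantile normalization. The count was 1304 without NoDox HE2 replicate 2, 1184 without NoDox HP replicate 2 and 369 in the 7 libraries low in Lars2. The TGF-beta and BMP response call was lost without NoDox HE2 replicate 2 (camera adjusted p = 0.0626) or NoDox HP replicate 1 (0.112), the integrated stress response call without the former (0.0577) and the cardiac mesoderm call without the latter (0.146).

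With doxycycline, HE2 again carried more blood transcripts than HE1. Tyrobp (relative log2 4.55 ± 0.28), Plek (4.31 ± 0.26), Ccl9 (4.05 ± 0.32), Spi1 (4.00 ± 0.27) and Myb (3.85 ± 0.51) were highest over HE1. Gprc5a (−2.41 ± 0.43), Cyp26a1 (−2.25 ± 0.26), Tnc (−2.23 ± 0.34) and Tagln (−2.18 ± 0.47) were lowest after Rps16 (−3.86 ± 0.78). Of 28 endothelial genes 2 were lower (7 adjusted over the list alone; relative median −0.59, camera adjusted p = 6.68e-07) and of 19 Notch and arterial genes 2 (3 adjusted over the list alone; −0.39, 0.000268). Of the blood lists, 24 of 27 pan-haematopoietic genes were higher (25 adjusted over the list alone; 1.22, camera adjusted p = 4.9e-20). The 13 list calls had adjusted p = 0.0664 to adjusted p = 0.785 with an estimated correlation. limma called 1144 genes, 759 higher and 385 lower, and the share higher was 66.3%, or 47.8% with quantile normalization and 41.1% with median scaling. The count was 512 without PlusDox HE1 replicate 2, 393 without PlusDox HE2 replicate 1, 642 without PlusDox HE2 replicate 2, 2354 with the class term and 11 in the 7 libraries low in Lars2. The DNA replication call was lost without PlusDox HE1 replicate 2 (camera adjusted p = 0.117) or PlusDox HE2 replicate 1 (0.381).

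From HE2 to HP with doxycycline, Cldn5, a claudin of endothelial junctions (log2 −5.30 ± 0.44), Edn1, endothelin (−4.84 ± 0.55), Madcam1, Clec14a and Nos3 (−4.56 to −4.47) were lowest in HP. Pf4 (4.62 ± 0.33), Tubb1 (3.48 ± 0.22), Cd52 (3.23 ± 0.29) and Tnni1 (3.2 ± 0.30) were highest. Scarna13, a small RNA gene, had a fold of 4.97 ± 1.48, with PlusDox HE2 at 27.1 ± 38.2 FPKM. Of the fixed lists, 26 of 28 endothelial (26 adjusted over the list alone; median −2.84, camera adjusted p = 1.55e-28) and 15 of 19 Notch and arterial genes (17; −2.57, 1.98e-16) were lower. Of 36 DNA replication genes 17 were higher (26 adjusted over the list alone; 0.67, camera adjusted p = 3.75e-12), as were 17 of 30 mitosis genes (22; 0.68, 1.41e-11) and 18 of 24 megakaryocyte genes (22; 1.80, 5.54e-18), with 1 lower. The 15 list calls had adjusted p = 0.0861 to adjusted p = 0.372 with an estimated correlation. limma called 2251 genes, 794 higher and 1457 lower, and the share higher was 35.3%, or 49.8% with quantile normalization. The count was 1329 without PlusDox HE2 replicate 2, 1307 without PlusDox HP replicate 2 and 9 in the 7 libraries low in Lars2. The mesenchymal call was lost without PlusDox HE2 replicate 2 (camera adjusted p = 0.139) or PlusDox HP replicate 1 (0.682) and with quantile normalization (0.0807) or median scaling (0.0614), and the TGF-beta and BMP response (0.161) and cardiac mesoderm (0.159) calls without PlusDox HP replicate 1.

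The same step was compared with and without doxycycline across genes. From HE1 to HE2, 368 genes such as Plek and Myb were called higher in both conditions, 208 such as Cyp26a1 and Tnc lower in both and 2 in opposite directions. Of the calls, 1280 of the 1348 genes called without doxycycline had the same sign with it. From HE2 to HP, 433 genes such as Pf4 and Tubb1 were higher in both, 992 such as Nos3 lower in both and 1 opposite, and 2065 of 2125 had the same sign. The Pearson r of the folds was 0.673 with a slope of 0.636 for the first step and 0.779 with a slope of 0.783 for the second, over 13316 genes that are not independent replicates and with no library shared. A slope below 1 also follows from error in the folds on the x axis. Differences between replicates of the NoDox and PlusDox groups correlated by number at 0.082, 0.489 and 0.436 in HE1, HE2 and HP.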

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

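The genes and lists given first are differences between populations in the effect of doxycycline that passed a test of the difference itself, while the 3 patterns after them were chosen for weighing. The comparison of replicate spread, the class term, the comparison of populations in fits that each lacked a library and the assignment of fusion reads were chosen after the result was seen. Leaving out each library was planned. Bounds for the class term and for the lowest HE2 count against the full fits were written before those tests. Between HE2 and HE1 the differences of log2 folds were 3.96 ± 0.55 for Il1b, 2.67 ± 0.38 for Ptprc, 2.16 ± 0.28 for Naaa, 1.80 ± 0.26 for Rhag, 1.69 ± 0.24 for Ctsj and −2.06 ± 0.27 for Tirap (SE; limma adjusted p = 0.0397 for each). Ptprc was listed at 0 in both NoDox HE1 libraries and Ctsj in all 6 NoDox libraries, so their values rest on the pseudocount. Between HP and HE2 they were −3.60 ± 0.44 for Ctsh and 2.83 ± 0.34 for Gm34865 (limma adjusted p = 0.0231). Between HP and HE1 they were 2.41 ± 0.34 for Gm34865, 2.40 ± 0.31 for Ramp2, 1.96 ± 0.26 for Rhag, −2.18 ± 0.32 for Mall and −2.73 ± 0.38 for Zfp185 (limma adjusted p = 0.048). Gm34865 and Mall were listed at 0 in both NoDox HP libraries. Lists differed between HE2 and HE1 for endothelial (median 0.52), Notch and arterial (0.37), pan-haematopoietic (0.37) and DNA replication genes (−0.24), by camera at the preset correlation. They differed between HP and HE2 for Notch and arterial (−0.37), erythroid (−0.27), megakaryocyte (0.36), DNA replication (0.34) and mitosis genes (0.28), and between HP and HE1 for endothelial (0.78) and stem-cell-associated genes (0.52). None of these list calls held with the estimated correlation (smallest adjusted p = 0.861, adjusted p = 0.922 and adjusted p = 0.97 with an estimated correlation, by camera), and the 4 between HE2 and HE1 were lost without NoDox HE2 replicate 1.

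More genes were called with doxycycline in HE2 (807) than in HE1 (182) or HP (111), which is not a test of a larger effect. Tests of the difference called 6 genes for HE2 against HE1 and 2 for HP against HE2. Of the 807 genes, 690 had the same sign in HE1 and 729 in HP. Of all tested genes, 67.1% had the same sign in HE2 and HE1 and 66.9% in HE2 and HP. Uneven carry-over of ribosomal RNA between the HE2 groups stays open. With a term for library class, used as its stand-in, HE2 had 1254 called genes and HE1, the larger of the other populations, 229. This cannot decide, since NoDox HE2 held no library high in Lars2 and the term was fitted mostly from HE1 and HP. The spread between replicates in HE2 was 1.03 times that of the other populations, but this check decides nothing. The fit pooled the spread over all groups, with a median SE of 0.225 in each population, so tighter HE2 replicates would not have favoured HE2. Whether a single HE2 library carries the excess stays open, since with one of their own libraries left out HE2 had 172 to 766, HE1 2 to 116 and HP 10 to 49 genes, and the lowest of HE2 was 1.48 times the highest of the others, just under the bound of 1.5. Against the full fits, the bound written beforehand, the lowest HE2 count fell below that of HE1, as a single deciding library predicts. That comparison is unequal, since leaving out one of its own libraries lowered the count in each population. A stronger response to the fusion, or to doxycycline itself, was not tested and stays open.

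In HP 4 of 28 endothelial genes rose (16 adjusted over the list alone), with a list median of 0.81 (camera adjusted p = 3.12e-17; adjusted p = 0.366 with an estimated correlation). HE1-type cells among the sorted HP cells would add all abundant HE1 transcripts in one proportion, and 66.7% of 48 such genes needed a share within 2 times of the median of 3.39%, between the bounds set for and against. The quartiles of the needed share were 1.76% and 5.31%, with Edn1 lowest at 0.156% and Thsd1 highest at 19.6%. A single share would give equal values apart from error, and the error of these shares was not estimated. Such cells, as the whole or a part of the rise, and a change in HP cells therefore cannot be told apart with these values. The sort gates are not given in the sources used here, and HE2-type cells were not tested as a source. Library class, the stand-in for uneven ribosomal carry-over, was balanced in HP, with 1 low and 1 high library in each doxycycline group. A difference between classes thus cancels from the fold. The medians of 0.88 in the low class and 0.72 in the high class each compare 1 library with 1. They decide nothing further. Retained endothelial transcription under the fusion or an effect of doxycycline itself was not tested.

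Mecom rose in HP with doxycycline by 5.14 ± 0.168 FPKM (SE). HE1-type cells were an unlikely source, since the Mecom level would need 25.3% of such cells against a median of 3.39% over 48 genes and a highest of 19.6%. Reads of the induced fusion assigned to Mecom should raise it in every population, and the rise in HP exceeded that in HE1 by 7.21 FPKM with a standard error of 6.16. The rise in HE2 (9.3 ± 4.03 FPKM) goes with such reads, while Hprt rose by 30.4 ± 12.9, 33 ± 1.31 and 60 ± 16.5 FPKM in HE1, HE2 and HP. Runx1, the gene of the other part of the fusion, changed by 0.00449 ± 1.84, −4.53 ± 8.12 and −23.1 ± 24.1 FPKM in turn. It gave no sign of fusion reads, but reads of a human cDNA may map only in part to mouse genes. Fusion reads and the mouse gene cannot be told apart here, because the spread in HE1 (−2.07 ± 6.16 FPKM) is as wide as the rise and the files hold no reads. Induction of the mouse Mecom gene itself was not tested and stays open.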

How the results depend on the processing

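All directions of the 126 called named genes other than Mecom held in every alternative, and 126, 123, 121, 119, 95, 73, 50 and 4 of them stayed called with no intensity trend, median scaling, quantile normalization, the class term, a pseudocount of 0.1, no filter, only the groups compared and without the 5 libraries high in Lars2. The held directions are weak support. The largest rises and falls were chosen with both libraries of one group above both of the other, so leaving out libraries could not turn them. These 126 are calls counted per population, so that a gene called in more than 1 population counts more than once. Where a value moved and fewer libraries or more genes do not explain it, the cause was not tested. Genes called in HE1, HE2 and HP numbered 182, 807 and 111, the differences HE2 against HE1, HP against HE2 and HP against HE1 6, 2 and 5, and the steps HE2 against HE1 and HP against HE2 1348 and 2125 without and 1144 and 2251 with doxycycline. Moved counts were 97 (HE1), 0 and 1 (the differences of HE2 from HE1 and of HP from HE2) with the pseudocount of 0.1, and 515 (HE2), 3 and 15 (HE2 against HE1 and HP against HE1) with no filter. Quantile normalization gave 351 in HE1, 1824 in HE2, 10 and 14 for the same differences, 2122 for HE2 against HE1 without and 2048 and 3394 for the steps with doxycycline, and passed Mecom in HE2 (1.05). Median scaling gave 1680 in HE2, 177 in HP, 1 and 10 for these differences, and 2062 and 1813 for HE2 against HE1 without and with doxycycline. No trend gave 10 for the difference between HE2 and HE1. A fold of at least 2 left 536 in HE2 and 772, 1331, 652 and 1349 in the steps. Fits to only the groups compared gave 2, 349 and 16 in HE1, HE2 and HP, 2 for the difference between HE2 and HE1, and 548 and 629 for that step without and with doxycycline. The estimated correlation left 0 of the 25 list calls with doxycycline. Scaling to TPM was not run.

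After seeing the data, the class term was added (1254 in HE2, 175 in HP, 1, 0 and 1 for the differences, 2354 for HE2 against HE1 with doxycycline, Runx1 in HE2 0.092). So was leaving out the 5 libraries high in Lars2 (0, 7 and 3 called, 0 for HP against HE1, steps 53, 369, 11 and 9, Mecom in HP 2.37, Runx1 0.12 in HE2 and 1.05 in HE1, similarity 0.373 for HE1 and HE2 and 0.175 for HE1 and HP). Replicate numbers did not pair samples by the labels, and 12 of 15 pairs of groups correlated above 0.1 by number (−0.1 to 0.526). A replicate block gave 459, 2296 (45.6% higher) and 305 in HE1, HE2 and HP, 47, 5 and 54 for the differences, 3126, 2420 and 3388 for the steps other than HP against HE2 without doxycycline, and passed Mecom in HE2 (0.98).

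Leaving out 1 library gave 2 to 191 (HE1), 172 to 877 (HE2), 10 to 124 (HP), 0 to 4, 0 to 5 and 0 to 7 (differences), 262 to 1424 and 1184 to 2195 (steps without doxycycline), 393 to 1137 and 1307 to 2331 (with) and 22 to 31 lists. Mecom ran from 2.36 to 2.44 in HP, 0.44 to 1.52 in HE2 and −0.45 to 0.25 in HE1 (0.065 without PlusDox HE1 replicate 2). Runx1 ran from −1.95 to 0.013 in HP, −0.60 to 0.12 in HE2 and −0.73 to 0.59 in HE1 (0.39 without NoDox HE1 replicate 1). Similarity ran from 0.419 to 0.557 (HE1 and HE2), 0.177 to 0.375 (HE1 and HP), 0.321 to 0.553 (HE2 and HP), and 0.523 to 0.716 and 0.680 to 0.805 (steps). The direction of the list test turned without NoDox HP replicate 1 for the myeloid (median 0.168, range 0.168 to 0.419) and interferon (−0.018, range −0.018 to 0.528) lists in HP and the megakaryocyte list in HP against HE2 (0.185, range 0.132 to 0.623). It turned without PlusDox HP replicate 1 for the erythroid list in HP against HE2 (−0.083, range −0.583 to −0.083). The absolute depth is unknown, and the relative depth of 0.581 in PlusDox HE1 replicate 2 limits weak genes most.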

Other observations

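The epithelial, growth factor and oxidative stress genes were picked after the result was seen, as was the test of the integrated stress response, and tests of such lists on the same data decide nothing. Several epithelial junction genes rose with doxycycline in both endothelial populations. Marveld2, a tight junction protein, went from 0.875 ± 0.138 to 6.23 ± 2.12 FPKM in HE1 (log2 1.92 ± 0.23) and from 0.527 ± 0.309 to 7.31 ± 0.128 in HE2 (2.46 ± 0.23). Krt18, a keratin of simple epithelia, went from 17.7 ± 0.231 to 50.0 ± 6.72 (1.44 ± 0.22) and from 17.2 ± 0.109 to 58.5 ± 3.07 (1.71 ± 0.22). Ocln, occludin, rose in HE2 from 2.71 ± 2.19 to 23.7 ± 2.73 FPKM (2.87 ± 0.35), and Lsr, Spint1 and Bcam rose in both (HE1 2.08, 1.99 and 1.65; HE2 2.23, 1.99 and 2.21). By limma 11 of 19 genes passed in HE1 (13 adjusted over the list alone). In HE2 12 passed (16 adjusted over the list alone). In HP only Cgn passed and was lower (−0.94 ± 0.18), with 10 higher and 1 lower adjusted over the list alone.

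Some genes of growth factor signalling also rose in HE1 and HE2. Egfr, the epidermal growth factor receptor, went from 2.64 ± 0.254 to 10.0 ± 0.490 FPKM in HE1 (log2 1.601 ± 0.19). Vegfc, a lymphatic and vascular growth factor, went from 6.19 ± 2.82 to 22.1 ± 3.89 in HE1 (1.73 ± 0.30) and from 4.41 ± 1.94 to 25.0 ± 3.24 in HE2 (2.31 ± 0.30). Etv4, Etv5, Dusp5 and Dusp9, targets of this signalling, rose by 1.84, 1.38, 1.54 and 1.62 in HE1 and by 1.58, 1.26, 1.57 and 1.34 in HE2, while Phlda1 fell in HE2 (−1.84 ± 0.30). By limma 8 of 18 genes rose in HE1 (8 adjusted over the list alone) and 10 did not pass. In HE2 8 rose and 1 fell (10 and 1 adjusted over the list alone). In HP 0 of 18 passed, with 8 higher and 1 lower adjusted over the list alone, and the medians were 0.65, 0.73 and 0.66 in HE1, HE2 and HP. Mt2 rose in HE2 (3.01 ± 0.52) as in HP. In all, 1, 2 and 2 of 17 oxidative stress and metallothionein genes rose in HE1, HE2 and HP (1, 2 and 3 adjusted over the list alone).

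A shift back towards earlier cells was tested as an account of the doxycycline effect. In HE2, the 1268 genes higher in NoDox HP than in NoDox HE1 had a median fold of −0.23 and 65.5% were lower, and the 1675 genes higher in HE1 had a median of 0.19 and 63.8% were higher, which left the hypothesis open. In HP, 415 genes higher in NoDox HE2 than in NoDox HE1 had a median of −0.056 and 357 genes higher in HE1 one of 0.22, which left it open there. In HE1, 375 genes higher in NoDox HP than in NoDox HE2 had a median of −0.01 and 956 genes higher in NoDox HE2 one of −0.078, with 43.3% of these higher. A stress response to doxycycline itself stays open. The integrated stress response list had medians from −0.35 to −0.10 over the 3 populations but 0.048 in the HE1 libraries low in Lars2, and the immediate early list had medians of 0.45, 0.56 and 0.62 in HE1, HE2 and HP and Nqo1 was called higher in all 3.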
